A study of Mus musculus with 6 samples.

How the data were processed

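The series measured RNA from laser-captured anterior-lobe prostate epithelium of male mice on 2-colour Agilent whole-genome oligonucleotide arrays of a custom design. Per the labels' protocols, about 5000 cells were captured per sample, total RNA was amplified in 2 rounds, and 825 ng of amplified RNA per sample was labelled with Cy3. A common reference pool, made of 10% prostate and 30% each of testis, liver and kidney RNA from Swiss-Webster mice, was labelled with Cy5 on every array. No dyes were swapped, so a dye effect that is specific to a probe is shared by both groups and drops out of their difference. Groups were taken from the labels of the Cy3 channel. The benign group held 3 Pb-Cre-negative Pten-floxed mice, and the tumour group held 3 Pb-Cre-positive Pten-floxed mice, all aged 28 to 30 weeks. The labels call the 3 samples of each group biological replicates.

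Per the file headers, the authors scanned and quantified the arrays with Agilent Feature Extraction 9.5.3.1, and the deposited mean and median background intensities of each spot are linear and not normalized between arrays. The processed signal intensity in the same deposited files is background-subtracted and dye-normalized by that program, per the file headers. The deposited log ratio of each spot is a log10 value of Cy5 over Cy3, and the deposited p-value of that log ratio comes from the program's own error model. The authors also deposited 1 table of log2 ratios for the whole series. Each of its values matched log2 of Cy3 over Cy5 processed signal to within 1.3e-06, and it was blank exactly where the program's p-value was 0.05 or more, so its scale, centring and direction were settled from the files. The medians of its 6 columns lay between 0.43 and 0.60, and 32.1% to 45.1% of the spots were blank.

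The log2 ratio of sample over reference was computed from mean and background intensities with limma 3.58.1 in R 4.3.3, by the normexp background correction with an offset of 50 and loess within each array. Control spots entered the background model and had weight 0 in the loess. Spots marked as non-uniform or population outliers in either channel were left out, and saturated spots were kept. Spots of 1 probe were averaged. A probe counted as above background on an array where more than 0.5 of its spots, or exactly that share, were well above background in the sample channel. It was tested if this held on at least 3 of the 6 arrays and at least 2 usable values remained in each group. Of 42204 probes, 29085 were tested. Probe names came from the files' accessions through the RefSeq table of GRCm38.p6 for 23583 probes and through a symbol or synonym for 9852, and the other 8769 kept the name in the files. Probe coordinates are those of the files, in build mm8.

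Pten-null and benign epithelium were compared with limma's linear model and moderated test, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05 on the adjusted p. All adjusted p-values of genes below are from this test unless another is named, and they rest on 3 mice against 3. An exact permutation test of a single value cannot go below 0.1 at this size, so none was used. Gene lists were compared with limma's camera at a preset correlation between genes of 0.01, with 1 probe per gene (the one brightest in the sample channel), members that had a value on all 6 arrays, and adjustment over the 27 of 28 lists with at least 5 such members. The camera test was repeated with the correlation estimated from the data, and with fry. Where a probe was not well above background on any array of 1 group, the fold is given as at least the stated number. It sets the bright group's mean against the dim group's floor, which is, on each array, the higher of the lowest signal among probes above background and the probe's own, after loess and Aquantile. The reference channel also read higher for some bright probes, so the same floor was set on the scale of the ratios, and the smaller of the 2 folds is given, a condition added after the values were seen. Such a bound is open to dye bias because no dyes were swapped. For some probes the smaller fold is that of the estimated ratios themselves, so it carries their error and is not a strict lower limit.

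The gene lists, the marker lists of other cell types, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among probes past the threshold whose groups did not overlap, with 1 probe per gene and only official-style symbols. It also took up to 4 members per list with the largest change among those past the threshold (2 if none passed), and 12 genes named in advance, which were Pten, Nkx3-1, Pbsn, Ar, Csf1, Il1b, Il6, Cxcl5, Arg1, Krt5, Krt8 and Ptprc. For a gene with several probes, the list value is that of the probe brightest in the sample channel, and probes of opposite sign are stated where a gene is named. The word median for a list refers to the log2 fold changes of its tested members.

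Alternatives replaced the background correction, the normalization, the filter on dim probes, the treatment of outlier spots, the variance model, the weights of the arrays, the threshold and the unit of testing, used the deposited log2 ratios, added blocks for slide and replicate number, and left out each array in turn. A run without the 2 arrays that had the fewest probes above background was chosen after seeing the data. The 6 arrays lay on 5 slides, of which 1 held benign replicate 1 and Pten-null replicate 2. With the slide as a fixed block no residual degrees of freedom remain, and limma's duplicateCorrelation returned no estimate for this layout. The random block therefore used the residual covariance of the 2 arrays on the shared slide over the mean residual variance, which was 0.189, and its list test took the moderated statistics of that fit. Pten-null replicate 1 was scanned on a day of its own, so the comparison within the other day is the one without that array.

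The scripts were tested on simulated data with the real probes' means and variances over 28147 probes. For Pten-null against benign epithelium, 49.3% of 67 probes changed 4-fold were recovered, 87.9% of 66 changed 16-fold and 1.49% of 67 changed 2-fold, with 7 false calls among 27947 unchanged probes. Only a small share of the simulated probes was changed, whereas 4064 of 29085 were called in the data. Fewer changed probes make the adjusted threshold stricter, so these percentages do not give the recovery in the data. Of 27 simulated lists, the 3 shifted ones were found and none of the others was called. The simulated probes varied independently, so this does not test camera on lists whose genes vary together. In the data, the estimated correlation was 0.43 for progenitor, 0.49 for macrophage and 0.83 for granulocyte markers, but -0.08 for luminal markers and 0.006 for p53 and senescence genes. The number of arrays limits the precision.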

Results

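Transcript levels were measured in epithelial cells captured by laser from the anterior prostate lobe of 3 mice with benign glands and 3 mice whose prostate epithelium had lost Pten, a lipid phosphatase that restrains PI3K and AKT signalling. The probasin-driven Cre recombinase (Pb-Cre) deletes the floxed Pten gene in prostate epithelium, and the benign mice carried the floxed gene without Cre. The title of the series places the comparison in a study of how Pten-null epithelium relates to myeloid-derived suppressor cells, which are immature myeloid cells that restrain T cells. Each array set 1 sample against a common RNA pool, and all values are log2 ratios of sample over pool. The median sample-channel signal was 7.51, 8.94 and 6.15 times the median background on the benign arrays. On the Pten-null arrays it was 11.3, 10.1 and 10.6 times, so every Pten-null array read higher than every benign one. The effect of this on the comparison was not tested. The number of probes above background was 30103, 21857 and 29231 on the benign arrays and 24026, 29749 and 29442 on the Pten-null arrays, so benign replicate 2 and Pten-null replicate 1 detected the fewest. Across tested probes, arrays correlated at 0.94 to 0.97 within the benign group, 0.86 to 0.92 within the Pten-null group and 0.76 to 0.80 between groups. These correlations are across probes, which are not independent replicates.

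Pten-null epithelium differed from benign epithelium at 4064 of 29085 probes, with 2275 higher and 1789 lower. The higher probes represented 1720 named genes and the lower ones 1250, with 15 genes holding probes of both kinds, among 16127 genes tested. Of the called probes, 214 were at least 16-fold higher and 95 at least 16-fold lower. The groups did not overlap at 36.6% of tested probes, against 10% by chance for 3 against 3. Leaving out benign replicate 1, 2 or 3 lowered the count to 1868, 1847 and 2185, and leaving out Pten-null replicate 1 lowered the fallen probes to 1119. Without the 2 arrays of lowest detection, an alternative chosen after seeing the data, 672 probes were called.

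The Pten gene itself was read by 5 probes on chromosome 19 (mm8, between 32874214 and 32891280), and none passed the threshold. Their log2 fold changes were -0.14, -0.43, -0.83, -0.99 and -1.40, with adjusted p from 0.053 to 0.92. The probe with the change of -1.40 ± 0.37 (SE, n = 3 per group) read 3.75 ± 0.16 (SD) in benign and 2.35 ± 0.69 in Pten-null epithelium, and it passed in 10 of 22 alternatives, among them those without Pten-null replicate 1 (adjusted p = 0.041) or replicate 2 (-1.02, adjusted p = 0.033), and its adjusted p ran from 0.021 to 0.17 over all of them. The probe at -0.99 passed in 3 of 21 and the probe at -0.83 in 2 of 21, among them that without Pten-null replicate 3 (-1.07, adjusted p = 0.034). The probe at -0.43 passed in 0 of 22 alternatives, with -0.034 without Pten-null replicate 3 and -0.18 without benign replicate 3. The probe at -0.14 turned to 0.40 without Pten-null replicate 2 and to 0.06 without replicate 3, and also turned positive under other scalings. The labels do not give the deleted part of the gene, so these probes do not check the genotype.

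Secreted prostate proteins were among the large falls. Tgm4, the prostate transglutaminase of the copulatory plug (probe at chromosome 9, 122916192 to 122916251, mm8), fell from 1.66 ± 0.14 to -7.05 ± 0.45 (SD, n = 3 each), a log2 fold change of -8.71 ± 0.28 (SE, adjusted p = 0.00018). Pbsn, the androgen-driven secretory protein probasin (chromosome X, 74097743 to 74097802), fell by 8.24 ± 0.40 (adjusted p = 0.00023). Outside the 10 largest falls, Nkx3-1, a homeobox gene of luminal prostate cells (chromosome 14, 68147577 to 68147636), fell by 5.18 ± 0.30, and Azgp1, a secreted glycoprotein, fell by 5.05 ± 0.30 (adjusted p = 0.00032 for each). The list of androgen-regulated and secretory genes was not shifted as a whole: of 19 tested members 7 rose, 4 fell and 8 did not pass, and the adjusted p of camera was 0.37. Its median log2 fold change was 0.65, its mean was -0.33 and camera pointed up, while fry pointed down (adjusted p = 0.038). Without Pten-null replicate 3 the median was 0.35. The members that rose included Ndrg1 (3.30 ± 0.29), Steap4 (3.16 ± 0.57) and the secreted protein Msmb (2.81 ± 0.58), picked as examples after their values were seen. Ar, the androgen receptor, read 0.45 ± 0.76 in benign and 1.04 ± 0.13 in Pten-null epithelium and did not pass (0.59, adjusted p = 0.38, and 0.15 without benign replicate 3). Adjusted over the list alone, 8 members rose and 4 fell, and the median between the 2 arrays of the shared slide was 0.65.

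Other large falls joined these. C1ra, a protease of the complement C1 complex, fell by 7.76 ± 0.29, and Fcgbp, a mucus protein that binds immunoglobulin, was at least 180-fold lower because no Pten-null array read it well above background. Mcoln3, a cation channel, was at least 60.2-fold lower on the same ground. Also lower were Glb1l3 (-6.52 ± 0.57), Olfr1148 (-6.09 ± 0.47), Nkd1, an inhibitor of Wnt signalling (-5.95 ± 0.91), Mest (-5.74 ± 0.81) and Adarb2 (-5.65 ± 0.29). Adjusted p for the 10 largest falls ran from 0.00018 to 0.0087.

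**Figure D1:**
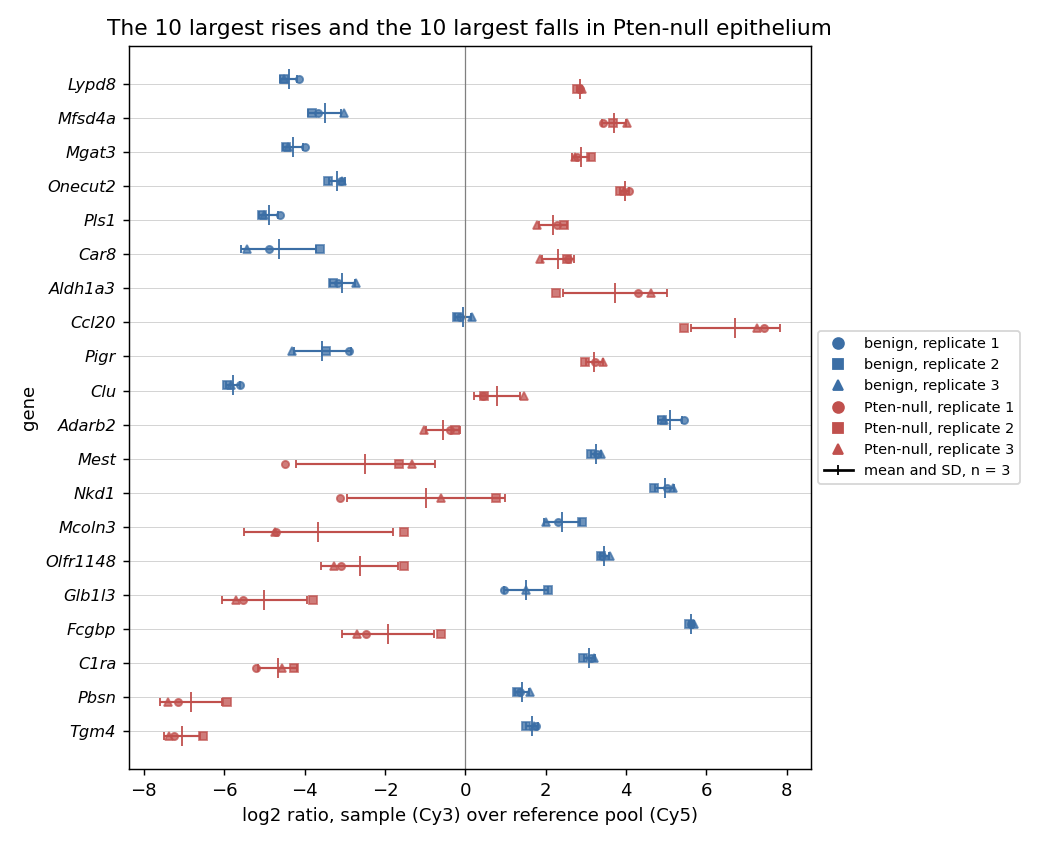
Log2 ratio of sample over reference pool (x axis) for the 10 genes with the largest rises and the 10 with the largest falls (y axis), with each replicate as a point and the mean and SD of n = 3 mice as a bar, benign in blue and Pten-null in red. The groups stand apart for all 20 genes, from Lypd8 with a log2 fold change of 7.24 to Tgm4 with -8.71.

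Lypd8, a glycoprotein secreted by colon epithelium (chromosome 11, 58202991 to 58203050, mm8), rose from -4.39 ± 0.21 to 2.85 ± 0.06, a log2 fold change of 7.24 ± 0.20 (adjusted p = 0.00016). Onecut2, a homeobox transcription factor, was at least 143-fold higher, and Mgat3, a glycosyltransferase, also at least 143-fold higher, since no benign array read them well above background. Both folds are those of the estimated log2 fold changes (7.16 for each). Mfsd4a rose by 7.21 ± 0.29, Pls1, an actin-bundling protein of microvilli, by 7.07 ± 0.26, Car8 by 6.95 ± 0.49 and Aldh1a3, an enzyme of retinoic acid synthesis, by 6.79 ± 0.62. Pigr, which carries polymeric immunoglobulin across epithelia, rose by 6.77 ± 0.38, and Clu, the chaperone clusterin, by 6.57 ± 0.32.

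Of 12 markers of proximal luminal progenitor cells, 8 rose and none fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 3.45. Clu, Nupr1 (5.08 ± 0.30), Wfdc2 (5.06 ± 0.18) and Ly6a (4.79 ± 0.57) led this list. The camera test gave it an adjusted p of 5.4e-08, and an adjusted p = 0.25 with an estimated correlation. Of general luminal markers, 7 of 12 were higher and none lower (8 and 1 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.0087, adjusted p = 0.25 with an estimated correlation). Elf3, an epithelial transcription factor, rose by 1.34 ± 0.19, Epcam by 1.47 ± 0.25, Prom1 by 1.94 ± 0.42 and Krt19 by 1.26 ± 0.21, and 1 of the 2 Krt8 probes passed, with 1.04 ± 0.20 (adjusted p = 0.018) against 0.51 ± 0.18 (adjusted p = 0.13). Epcam (adjusted p = 0.058) and Krt19 (adjusted p = 0.061) lost their calls without benign replicate 1, Prom1 without any array but Pten-null replicate 2 (adjusted p from 0.062 to 0.107), and Krt8 without any benign array or Pten-null replicate 1 (adjusted p from 0.0501 to 0.077). The list call ended when loess was replaced by median centring (adjusted p = 0.22). The basal markers were not shifted (4 of 14 rose, 1 fell, camera adjusted p = 0.33), with Lamb3, a laminin chain, 1.94 ± 0.18 higher. Krt5 read 2.25, -1.29 and 1.61 on the 3 Pten-null arrays against 1.67 ± 0.15 in benign epithelium (adjusted p = 0.60), and without Pten-null replicate 2 the basal list passed (adjusted p = 0.015) and the Krt5 difference turned from -0.81 to 0.27. Between the 2 arrays of the shared slide, the list medians were 3.30 for progenitor, 0.85 for luminal and -0.33 for basal markers.

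Of the interferon response genes, 19 of 23 rose and none fell (20 and 0 adjusted over the list alone), with a median of 2.71. Oas2 rose by 4.76 ± 0.18, Ifi44 by 4.72 ± 0.29 and Ifit1 by 4.65 ± 0.28, all of them antiviral genes induced by type I interferon. Cxcl10, an interferon-induced chemokine, was at least 22.4-fold higher (adjusted p = 0.037), with -0.25 on the array of Pten-null replicate 2 and 4.26 and 3.66 on the other Pten-null arrays, and its call was lost without any array but Pten-null replicate 2 (adjusted p from 0.092 to 0.13). The camera adjusted p was 5.9e-14, and adjusted p = 0.25 with an estimated correlation. Genes of antigen presentation on MHC class I also rose, 7 of 11 with none lower (9 and 0 adjusted over the list alone) and a median of 0.98, among them the immunoproteasome subunit Psmb8 (2.74 ± 0.29), H2-K1 (1.15 ± 0.26), Psme1 (1.08 ± 0.19) and Tapbp (0.98 ± 0.18). That list had a camera adjusted p of 0.00016, and adjusted p = 0.25 with an estimated correlation. The call of H2-K1 was lost without any array but Pten-null replicate 2, that of Tapbp without any benign array or Pten-null replicate 1, and that of Psme1 without any benign array (adjusted p from 0.052 to 0.123). In the runs without 1 array, the log2 fold change ran from 0.996 to 1.32 for H2-K1, 0.92 to 1.02 for Tapbp and 1.02 to 1.16 for Psme1. The MHC class II list was not shifted (1 of 10 rose, camera adjusted p = 0.13), although Ctss, a lysosomal protease, rose by 3.57 ± 0.43, and it passed without Pten-null replicate 2 (adjusted p = 0.012). Medians between the arrays of the shared slide were 2.34 for interferon genes, 0.87 for class I and -0.08 for class II.

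**Figure D2:**
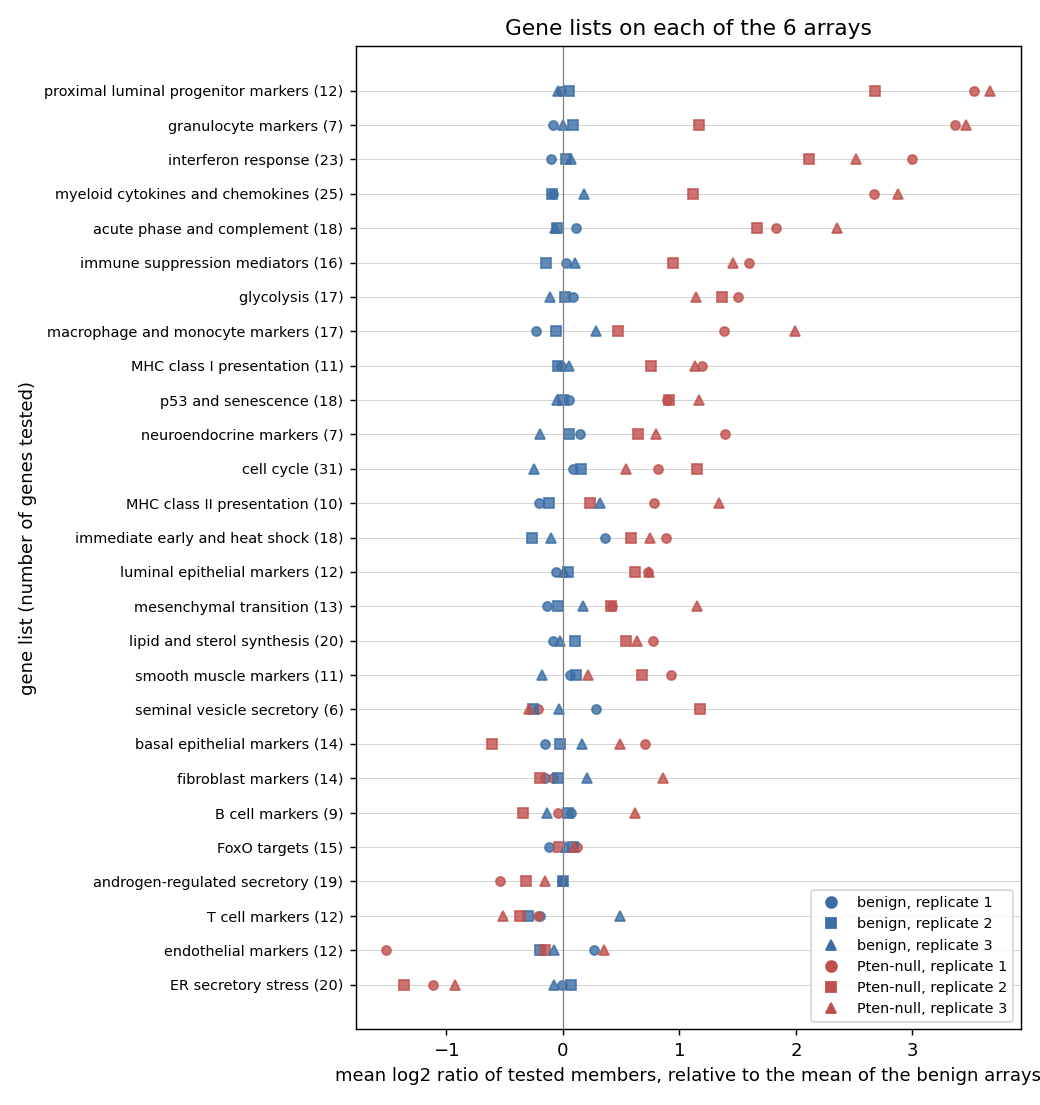
Mean log2 ratio of the tested members of each gene list, relative to the mean of the benign arrays (x axis), for the 27 lists with at least 5 tested members (y axis, number of genes tested in brackets), with 1 point per array, benign in blue and Pten-null in red. The 3 Pten-null arrays score 2.68 to 3.67 on progenitor markers and -0.93 to -1.36 on secretory stress genes, and Pten-null replicate 2 scores lower than the other Pten-null arrays on myeloid cytokines (1.12 against 2.67 and 2.88).

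Secreted signals to myeloid cells were the list closest to the question of the series. Of 25 tested myeloid cytokines and chemokines 10 rose, 1 fell and 14 did not pass (13 higher and 1 lower adjusted over the list alone), with a median of 1.89. Ccl20, which attracts CCR6-bearing cells, was at least 79.1-fold higher (adjusted p = 0.00083). Spp1, the secreted phosphoprotein osteopontin, rose by 4.34 ± 0.54, and Cxcl1, a neutrophil attractant, rose by 3.79 ± 0.67, which did not pass without benign replicate 1, 2 or 3 (adjusted p from 0.052 to 0.060). The list had a camera adjusted p of 1.9e-06, and adjusted p = 0.25 with an estimated correlation. Its median was 0.89 between the 2 arrays of the shared slide, so it moved by over 1.5 times there. That comparison sets 1 array against 1, and its Pten-null array is replicate 2, which scored lowest on this list (1.12 against 2.67 and 2.88). An effect of the slide cannot be told apart from the values of that mouse.

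Several myeloid factors named in advance differed among the Pten-null mice. Cxcl5, another neutrophil attractant, read 6.71, 2.01 and 6.74 on the Pten-null arrays and -0.64 and -0.70 on the 2 usable benign arrays, with a log2 fold change of 5.82 ± 1.51 (SE) and an adjusted p of 0.063. Without Pten-null replicate 2 the change was 7.40 (adjusted p = 0.0004). Il1b read 4.47, 0.01 and 4.38 against -0.37, -0.87 and 1.95 in benign epithelium, a difference of 2.71 ± 1.35 (adjusted p = 0.24) that became 4.18 without Pten-null replicate 2 (adjusted p = 0.025). In the other runs without 1 array that gave a value, neither Cxcl5 nor Il1b passed (adjusted p from 0.089 to 0.48). Csf1, the macrophage growth factor, differed by 0.83 ± 0.43 (adjusted p = 0.27), by 1.27 without Pten-null replicate 2 (adjusted p = 0.033) and by 0.45 without Pten-null replicate 3 (adjusted p = 0.51). Arg1, an arginine-degrading enzyme of suppressor myeloid cells, differed by 2.16 ± 0.92 (adjusted p = 0.19), and by 1.07 without Pten-null replicate 1. The Il6 probe was not well above background on any array and was not tested.

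**Figure D3:**
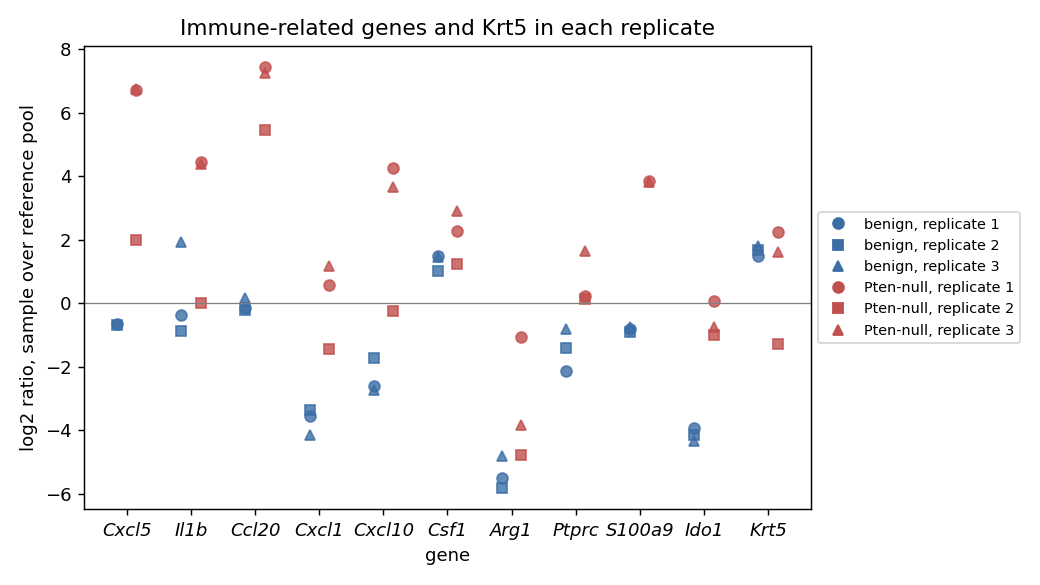
Log2 ratio of sample over reference pool (y axis) of 11 genes (x axis), with 1 point per replicate, benign in blue and Pten-null in red, and missing points where a spot was not usable. Pten-null replicate 2 reads 0.01 for Il1b and 2.01 for Cxcl5, below replicates 1 and 3, which read 4.47 and 4.38 for Il1b.

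Mediators of immune suppression split in direction. Of 16 tested, 5 rose and 2 fell, also when adjusted over the list alone, with a median of 1.24 (camera adjusted p = 0.039, adjusted p = 0.41 with an estimated correlation). Lgals9, a galectin that binds T cells, rose by 4.51 ± 0.25, Nt5e, the ectonucleotidase CD73, by 3.87 ± 0.36, and Ido1, which degrades tryptophan, by 3.59 ± 0.32. Ptgs2, the inducible cyclooxygenase, was at least 8.98-fold higher (adjusted p = 0.028), a call lost without any benign array or Pten-null replicate 1 (adjusted p from 0.056 to 0.106). The list call was lost without benign replicate 1 (adjusted p = 0.052), Pten-null replicate 1 (adjusted p = 0.075) or Pten-null replicate 3 (adjusted p = 0.16), and its direction turned when only probes above background on all 6 arrays were used (median -0.16, adjusted p = 0.75) and with the deposited log2 ratios (median 0.35, adjusted p = 0.98). The filter on all 6 arrays leaves out probes that no benign array read well above background, such as the called Ptgs2 probe. That median of -0.16 is therefore not over the same members. The list's median within the shared slide was 0.63.

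Lists of macrophage and granulocyte markers were shifted up, and those of T and B cells were not. Of 17 macrophage and monocyte markers 4 rose and none fell, also when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 0.0011, adjusted p = 0.45 with an estimated correlation). That median was 0.40 without Pten-null replicate 3, 1.26 without benign replicate 3 and 1.502 without Pten-null replicate 2. The 4 were Mrc1 (3.54 ± 0.25), Lyz2 (3.45 ± 0.28), Cd14 (2.45 ± 0.31) and Ptprc, the pan-leukocyte antigen CD45 (2.12 ± 0.52, adjusted p = 0.043), whose call was lost without any array but Pten-null replicate 2 (adjusted p from 0.064 to 0.14). Of 15 granulocyte markers on the array only 7 could be tested, and 3 of these rose. They were Ltf (5.09 ± 0.54), Ly6c1 (4.66 ± 0.46) and S100a9, a calcium-binding protein of neutrophils and stressed epithelium, at least 25.1-fold higher (n = 2 usable Pten-null arrays). The array without a usable S100a9 value was Pten-null replicate 2, which scored lowest on myeloid cytokines (1.12 against 2.67 and 2.88). The S100a9 value thus rests on Pten-null replicates 1 and 3. Adjusted over the list alone, 4 rose. The granulocyte median was 4.31, or 3.93 with S100a8 and S100a9 at their bounds, and 2.80 over the 6 members in the camera test. Without Pten-null replicate 2 that median was 4.65. S100a9, not usable on that array, then joined the members, and 4.65 is its own log2 fold change. The medians with and without that array thus rest on different members. The list had a camera adjusted p of 0.039 (adjusted p = 0.53 with an estimated correlation), and its call was lost without benign replicate 1 (adjusted p = 0.052), Pten-null replicate 1 (adjusted p = 0.099) or Pten-null replicate 3 (adjusted p = 0.13), and with fry (adjusted p = 0.052). The T cell list held 1 faller among 12, Lck (-1.72 ± 0.37), and the B cell list no call among 9, with Jchain at 2.23 (adjusted p = 0.16, but 3.01 and adjusted p = 0.022 without Pten-null replicate 2) and Ms4a1 at -2.14 (adjusted p = 0.15, but -3.13 and adjusted p = 0.011 without benign replicate 3). Neither list was shifted (camera adjusted p = 0.24 and 0.58). Lck did not pass without any benign array or Pten-null replicate 1 (adjusted p from 0.064 to 0.11). Medians within the shared slide were 0.28 for macrophage, 0.75 for granulocyte, -0.42 for T cell and -0.32 for B cell markers.

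Acute phase and complement genes rose in 10 of 18 cases and fell in 2 (12 and 2 adjusted over the list alone), with a median of 3.37, or 3.30 with dim genes at their bounds (camera adjusted p = 3.6e-05, adjusted p = 0.25 with an estimated correlation). Cfb, complement factor B, rose by 5.38 ± 0.34 and Saa2, serum amyloid A, by 4.65 ± 0.50, while C1ra and C1s1 (-5.21 ± 0.42), both proteases of the C1 complex, were lower. The second C1s1 probe had the opposite sign, at 2.27. The list call ended with the deposited log2 ratios (adjusted p = 0.12), and the median within the shared slide was 1.46.

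Metabolic and growth lists moved as follows. Glycolysis genes rose in 12 of 17 cases with none lower (13 and 1 adjusted over the list alone) and a median of 1.24, led by hexokinase Hk2 (3.72 ± 0.22), the lactate carrier Slc16a3 (2.52 ± 0.25), Pfkp (2.49 ± 0.31) and Pfkl (1.99 ± 0.31), with a camera adjusted p of 8.7e-08 and an adjusted p = 0.25 with an estimated correlation. Cell cycle genes rose in 9 of 31 cases with none lower (14 and 0 adjusted over the list alone) and a median of 0.77 (camera adjusted p = 1.5e-05, adjusted p = 0.28 with an estimated correlation), among them Mcm3 (2.16 ± 0.30), Birc5 (2.00 ± 0.47), Mki67 (1.90 ± 0.47) and Tpx2 (1.62 ± 0.31). Of these 4 calls, only that of Mcm3 held without each single array, and the others had adjusted p up to 0.14. Lipid and sterol synthesis genes rose in 5 of 20 cases with none lower (5 and 1 adjusted over the list alone) and a median of 0.67 (camera adjusted p = 0.0087, adjusted p = 0.25 with an estimated correlation), with Dhcr24, the last enzyme of cholesterol synthesis, at 2.96 ± 0.32, and Hmgcr, Scd2 and Ldlr between 0.98 and 1.36, although the other Hmgcr probes ran from -0.23 to 0.55. Calls of those last 3 were lost without any array but Pten-null replicate 2, with adjusted p up to 0.14. The lipid list lost its call with median centring (adjusted p = 0.13), with the slide as a random block (adjusted p = 0.071) and with the deposited log2 ratios (adjusted p = 0.12). Medians within the shared slide were 1.13, 0.87 and 0.61 for these 3 lists.

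Genes of protein folding and secretion in the endoplasmic reticulum were the only list shifted down, with 9 of 20 lower, none higher and a median of -1.19 (camera adjusted p = 1.5e-07, adjusted p = 0.25 with an estimated correlation). Sdf2l1 fell by 2.23 ± 0.22, the chaperone Hyou1 by 1.92 ± 0.28, Creld2 by 1.86 ± 0.28 and the disulfide isomerase Pdia4 by 1.80 ± 0.38, although Pdia4 did not pass without benign replicate 1, 2 or 3 (adjusted p from 0.078 to 0.104). Adjusted over the list alone, 16 members fell. The median within the shared slide was -1.35.

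Genes of p53 and senescence rose in 5 of 18 cases and fell in 1 (7 and 2 adjusted over the list alone), with a median of 0.56, and the list missed the threshold (camera adjusted p = 0.055, adjusted p = 0.25 with an estimated correlation). The members that rose included the cell cycle inhibitors Cdkn2b (5.11 ± 0.37) and Cdkn1a (2.32 ± 0.36), the cell death gene Pmaip1 (4.76 ± 0.37) and the kinase Plk2 (3.21 ± 0.34). The list passed in 11 of 24 alternatives, among them fry (adjusted p = 0.0019) and those without benign replicate 2 (adjusted p = 0.041), benign replicate 3 (adjusted p = 0.048) or Pten-null replicate 2 (adjusted p = 0.025). Without Pten-null replicate 3 its median was 0.32 (adjusted p = 0.18). FoxO targets, genes of transcription factors that AKT holds back, were not shifted (2 of 15 rose and 3 fell, 5 and 3 adjusted over the list alone, camera adjusted p = 0.81), with a median of -0.35, a mean of 0.07 and fry pointing up. Medians within the shared slide were 0.16 for p53 and senescence genes and -0.26 for FoxO targets. Txnip, which limits glucose uptake, rose by 3.57 ± 0.25, and Gadd45a by 1.56 ± 0.30, while Klf2 (-1.80 ± 0.46) and Sesn3 (-1.36 ± 0.33) fell, although the other Klf2 probe read -0.00815. Among these, Gadd45a was called without benign replicate 1 or 3 or Pten-null replicate 2, and was lost without the others (adjusted p from 0.052 to 0.062). Klf2 and Sesn3 were lost without any benign array or Pten-null replicate 1, and Klf2 also without Pten-null replicate 2 (adjusted p from 0.053 to 0.15).

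Immediate early and heat shock genes, which can respond to tissue handling, had 3 of 18 higher and 2 lower (8 and 2 adjusted over the list alone) with a median of 1.08 (camera adjusted p = 0.013, adjusted p = 0.41 with an estimated correlation). Fos rose by 1.71 ± 0.43 and Jun by 1.45 ± 0.30, while Nr4a1 fell by 2.22 ± 0.29 and Atf3 by 1.37 ± 0.30. The calls of Fos, Jun and Atf3 were each lost without some single array, with adjusted p up to 0.15, and the list call was lost with median centring (adjusted p = 0.077), the deposited log2 ratios (adjusted p = 0.079) and the slide as a random block (adjusted p = 0.23). Their median within the shared slide was 0.24.

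Of the mesenchymal transition genes 4 of 13 rose and 2 fell without a shift of the list (camera adjusted p = 0.29), with Itgb6 (4.11 ± 0.44), Mmp14 (2.34 ± 0.26) and Fn1 (1.99 ± 0.48) higher and Zeb1 (-1.95 ± 0.47) lower. Calls of Fn1 and Zeb1 were each lost without some single array, with adjusted p up to 0.13. Markers of other cell types in the gland gave few calls. Fibroblast markers had 1 riser of 14, Fbln1 (1.97 ± 0.44, up to an adjusted p of 0.107 without single arrays), endothelial markers 1 faller of 12, Emcn (-3.72 ± 0.58), and neuroendocrine markers 1 riser of 7, Chgb (4.47 ± 0.46), with camera adjusted p of 0.58, 0.42 and 0.44. Smooth muscle markers passed narrowly (1 of 11 rose, 4 adjusted over the list alone, Actg2 at 1.51 ± 0.35, median 0.56, camera adjusted p = 0.046, adjusted p = 0.45 with an estimated correlation), and that call was lost without benign replicate 1 or 3 or Pten-null replicate 1 or 2 (adjusted p from 0.065 to 0.12). It was also lost with fry, with the slide block and under each other scaling except Aquantile, and on probes above background on all 6 arrays (adjusted p up to 0.45). Among the runs without 1 array, the call of Actg2 held only without Pten-null replicate 2, with adjusted p up to 0.124 in the others. Seminal vesicle secretory genes had no call among 6 (Svs4 0.69 and Svs5 0.47, or 0.19 and 0.24 without Pten-null replicate 2, camera adjusted p = 0.58), and the 3 tested erythrocyte markers none, too few for camera (Alas2 -0.55, or -0.17 without Pten-null replicate 1 and -0.87 without benign replicate 3, and Slc4a1 -0.16, or -0.0187 without Pten-null replicate 1 and -0.44 without Pten-null replicate 2). Medians within the shared slide were -0.02 for mesenchymal transition, -0.36 for fibroblast, 0.05 for endothelial, 0.18 for neuroendocrine, 0.57 for smooth muscle and 0.92 for seminal vesicle genes.

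Over the 27 lists tested together, 14 were shifted up and 1 down by camera with the preset correlation, and none passed with the correlation estimated from the 6 arrays, where 5 had an unadjusted p under 0.05. The loss of calls there does not measure correlation alone. Luminal markers had an estimated correlation of -0.08, below the preset 0.01, yet their unadjusted camera p went from 0.0035 to 0.037. For p53 and senescence genes, with an estimated 0.006, it went from 0.033 to 0.093. By fry, 15 lists passed. Among the genes named above with a probe that passed, Fn1, Hmgcr, Klf2, Krt8, Lyz2, Mki67, Pfkp, Ptgs2, Sesn3 and Txnip also had probes that did not pass. Without the 2 arrays of lowest detection, 12 lists passed.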

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

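The run without the 2 arrays of lowest detection was chosen after seeing the data. The main count was 4064 probes, 2275 higher and 1789 lower. The lower count was 2913 at an adjusted p under 0.10, 2761 from the sample channel alone (2582 higher, so the excess turned) and 1162 with genes in place of probes, where fewer features were tested. On probes above background on all 6 arrays, 1724 were higher and 1726 lower. Array weights gave 6563 probes, 3153 of them lower. Leaving out 1 array gave 1847 to 5692 probes, 1203 to 3010 higher and 644 to 2682 lower, the most without Pten-null replicate 2. Without the 2 arrays of lowest detection there were 672, 465 and 207, with fewer arrays. Camera called 15 lists, 0 with an estimated correlation (fry 15) and 12 to 17 without 1 array. Of 96 called named probes, 42 held in every alternative that gave a value, and none turned sign; 23 were lost with median centring, 12 with the deposited log2 ratios, 12 with no filter on dim probes, 11 with the processed signals and 54 without the 2 arrays of lowest detection. Signal over background was 6.15 to 8.94 on the benign arrays and 10.1 to 11.3 on the Pten-null arrays. In all, 13119 probes were too dim or too often unusable to test.

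With the replicate number as a block, 2487 probes were called, 1542 higher and 945 lower, and 23 calls of named probes did not pass. Same-numbered samples deviated together at -0.01, 0.02 and 0.09, none over 0.1, so the numbers were not taken to pair the samples. Benign samples 2 and 3 correlated best with their own number, and benign sample 1 with Pten-null sample 2, which shares its slide.

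The cause of the turns in sign or direction below was not tested. The Pten probe at -0.14 read 0.0851 with the processed signals and the deposited log2 ratios, 0.24 without background subtraction, 0.0609 with median centring, 0.43 with array weights and -0.88 to 0.40 without 1 array (positive without Pten-null replicate 2 or 3). Krt5 read 4.99e-05 with array weights and -1.504 to 0.27 without 1 array (positive without Pten-null replicate 2), and Slc4a1 0.0871 with median centring. For lists, the test's direction turned with these medians. FoxO targets had -0.35 with fry, -0.32 without background subtraction, -0.44 from the sample channel alone, -0.22 with the deposited log2 ratios, -0.36 with the slide block and -0.35 to -0.19 without 1 array (turned without benign replicate 2, at -0.29). Androgen-regulated genes had 0.65 with fry and with the slide block, and 0.24 on probes above background on all 6 arrays. Immune suppression had -0.16 on those probes and 0.35 with the deposited log2 ratios. Probes that only 1 group read well above background are left out by the filter on all 6 arrays. The list medians under that filter therefore do not rest on the same members as the main ones. Seminal vesicle genes had -0.00194 with the processed signals and the deposited log2 ratios, -0.0515 without background subtraction, -0.0767 from the sample channel alone, 0.21 with array weights and -0.27 to 0.48 without 1 array (lowest and turned without Pten-null replicate 2). Fibroblast markers had -0.0372 without background subtraction and -0.29 to 0.72 without 1 array (lowest and turned without Pten-null replicate 3). B cell markers had -0.32 to 0.0872 without 1 array (turned without benign replicate 2, at -0.0576, and Pten-null replicate 2, the highest). Endothelial markers had -0.76 to 0.35 without 1 array (highest and turned without Pten-null replicate 1) and 0.17 without the 2 arrays of lowest detection.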

Other observations

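The tests of gene families, intestinal genes, leukocyte transcripts, luminal markers and androgen-regulated genes were chosen after the main results were seen, and those of the luminal markers and androgen-regulated genes after their own values were seen. Some genes of intestinal epithelium rose in Pten-null epithelium, picked here for their rise. Vil1, an actin-bundling protein of the brush border, rose by 6.16 ± 0.27, and Reg1, a secreted lectin-like protein, by 5.32 ± 0.22. Cdh17, the liver-intestine cadherin, was at least 31.7-fold higher, Krt20, a keratin of intestinal cells, at least 43.0-fold and Clca1, a goblet cell protein, at least 90.0-fold, since no benign array read them well above background. Of 37 tested genes of a wider list of 40, 13 rose, 2 fell and 22 did not pass, with a median of 1.08. The risers included Hnf4a, a transcription factor of gut and liver (4.58 ± 0.42), Lgals4 (2.52 ± 0.23) and Anpep (2.41 ± 0.23), and the fallers were Slc26a3 (-4.84 ± 0.96) and Lct, at least 8.75-fold lower.

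Among 190 families formed from the letters of gene symbols, several moved together by camera, and each family named here had an adjusted p = 0.96 with an estimated correlation. Interferon-inducible Ifi genes rose in 10 of 14 cases (adjusted p = 1.0e-05). Caspases rose in 5 of 11 cases (adjusted p = 0.015), with Casp1 (5.01 ± 0.26) and Casp4 (3.00 ± 0.40), which act in inflammatory cell death. Carboxylesterases rose in 6 of 14 cases (adjusted p = 0.015), mucins in 4 of 11 cases, with Muc4 at 5.52 ± 0.34 (adjusted p = 0.025), and myosins in 9 of 22 cases, with Myo7b at 2.55 ± 0.25 and Myo1a at 2.27 ± 0.37 (adjusted p = 0.036). Olfactory receptors were lower in 25 of 402 cases and higher in 2, no larger a share lower than the 1250 of 16127 genes tested, with a median of -0.29 (adjusted p = 1.0e-05) that was -0.07 with median centring. The medians of these families kept their sign under each scaling compared.

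The rise of intestinal-type genes was noticed in 10 genes picked for it, with a median of 5.83 (95% bootstrap interval 5.32 to 6.62), or 5.79 with dim genes at their bounds. Intestinal tissue among the captured material would bring abundant intestinal transcripts up as well. Of 20 such transcripts 6 rose, 2 fell and 12 did not pass, with a median of 0.97 (0.20 to 2.26). The bound written beforehand, an upper limit below 5.83, was met. It cannot decide the question, because the 10 genes were picked for their rise and a list not so picked would tend to lie lower. A broader intestinal programme in Pten-null epithelium is a candidate explanation: the list of 40 genes, written before its members' values were seen, was shifted up by camera (adjusted p = 0.000197, adjusted p = 0.22 with an estimated correlation), but the 20 abundant transcripts are among its members and were shifted up too (adjusted p = 0.0025), so this shift alone does not separate the explanations. The list scored 1.18, 1.77 and 0.32 on the 3 Pten-null arrays relative to benign. A change of cell type within the captured epithelium stays open and was not tested.

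Myeloid cytokine genes rose in 10 of 25 cases, and leukocytes taken up with the captured epithelium could account for part of this. Abundant leukocyte transcripts had a median of 1.17 (0.60 to 2.28), with 8 of 21 higher and 1 lower (camera adjusted p = 0.0008, adjusted p = 0.22 with an estimated correlation), against 2.62 (1.90 to 4.35) for the called myeloid cytokine genes. The bound written beforehand, an upper limit of 2.28 below 2.62, was met, but it was wrong because it ignored the spread of the cytokine genes, which were themselves picked for being called, so it was replaced after the result by a comparison of the intervals, which overlap. Srgn (5.80 ± 0.36) and Ctss (3.57 ± 0.43) rose, while Coro1a (1.17, adjusted p = 0.27) and Lcp1 (-0.76, adjusted p = 0.15) did not pass and Cd52 fell by 1.59 ± 0.26. Epithelial expression and leukocytes cannot be told apart for these genes here.

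The loss of Pbsn, Tgm4, Nkx3-1 and Azgp1 had a median of -6.71 (-8.71 to -5.05). A smaller share of luminal epithelium would lower luminal markers as far, but these had a median of 0.85 (-0.01 to 1.30). That list holds general luminal markers, so it cannot exclude a change from some luminal cells to others. Markers of proximal luminal progenitor cells rose, with a median of 3.45. A general fall of androgen-regulated genes would lower the called members of that list, but 63.6% of them rose. That share was known before the test was written, so it is a description and not a new test. The mean of the list was -0.33, and fry pointed down (adjusted p = 0.038). A selective loss of these secretory and luminal genes in Pten-null epithelium stays open as a hypothesis. A change in the kinds of luminal cells captured stays open as well, and neither was tested.

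Other splits of the 6 arrays into 3 and 3 were counted for the whole result. In 1 of 10 splits, the real one, 4064 probes were called, and the highest of the others was 0, but 10 splits are too few for a share under 0.05. For lists, 3 of 10 splits gave at least the real 15, and the others gave 4 to 16, the highest in the splits that put Pten-null replicate 2 with benign replicates 1 and 2 or 1 and 3. The real count of lists thus did not exceed that of every other split, so it does not set the real grouping apart. Each other split puts 2 arrays of 1 group with 1 array of the other, so part of the real difference stays in it. The counts of the other splits are therefore not those of arrays without a group difference.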
